A study of Homo sapiens with 8 samples.

How the data were processed

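The series holds 8 libraries from human melanoma cell lines grown for 72 h, with or without 1 µg/ml doxycycline to induce hairpins, crosslinked with PFA and EGS and processed with a commercial Hi-C and HiChIP kit, per the labels' protocols. The submitters' processing notes name HiC-Pro, MACS2 and the builds hg38 and mm10, without versions or the role of each. Coordinates below are hg38, the build whose annotated promoters the target windows matched.

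The deposited H3K27ac HiChIP files give counts of contacts per pair of anchors, in whole numbers with no normalization, for 4 A375 libraries. They include contacts within an anchor and between chromosomes. The deposited Hi-C files give a fraction, a score of a 500 bp element for a 500 bp target window, between 0.02 and 1, with how it was made not stated. Their sequencing depth is unknown, so no interval was given for scores. The IgG HiChIP library was not analysed here.

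The design, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. Promoters were taken as target windows whose midpoint lay within 1000 bp of an end of a RefSeq protein-coding gene, nearer to it than to the other end by 100 bp. Of 19974 genes, 15472 were placed this way and 812 by a window inside the gene. Both ends were used for 3690 genes, because the annotation used gives no strand. A loop joined different anchors on 1 chromosome, and a gene's count was the sum over loops with an anchor within 2500 bp of its promoter, each loop counted once. Genes with the same loops carry the same counts and were named together.

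Counts were tested with edgeR 4.0.16 (R 4.3.3; TMM, filterByExpr, glmQLFit and glmQLFTest) for the 2 shHOXD13 against the 2 shNTC libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The hairpins were treated as replicates of 1 knockdown. Standard errors were derived from the fold change and the test statistic. Genes at 0 in a group were given a lower bound of the fold against a floor of 3 contacts over the group. Pairs of anchors were matched by 10 kb bins of their midpoints, since under 90% of anchors were identical. Gene lists were tested with limma 3.58.1 camera on log2 counts scaled to library totals (preset correlation 0.01), adjusted over 10 lists with at least 3 tested members, with an estimated correlation and fry beside it. Loop spans were compared with an exact permutation test. The p-values measure the spread between these libraries alone, since the labels do not say whether replicates are separate cultures.

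Because anchors differed between libraries, counts were repeated after the data were seen between anchors merged where they overlapped, and between the 23637 of 66045 merged anchors held by all 4 libraries. Further settings chosen then used contacts within anchors, contacts between chromosomes, loops under 2 Mb, only genes placed by a window, scaling to all contacts on 1 chromosome, and offsets fitted to gene density. Settings fixed earlier were DESeq2 1.42.0, library size only, loess offsets, other count filters, promoter windows of 1000 and 5000 bp, loops with at least 2 contacts or spanning at least 20 kb, loops present in all 4 libraries, thinning to equal totals, a likelihood ratio test and leaving out each library. Where 1 library remained in a group, it was assumed to vary like the other group.

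For the lines, scores were summed per promoter window, using for each gene the window with the highest sum over the 3 lines, after exact repeats (254, 264 and 259 links) were removed. Log2 ratios used the lowest listed score, 0.020, as pseudocount. List medians were set against 10000 random lists matched on mean summed score in 20 bins. Alternatives were 10 times the pseudocount, the highest score or the number of links in place of the sum, the upper part of the scores above the median, and sums divided by the line's median. Links were shared when their target windows overlapped and their elements overlapped, each by at least 1 bp. Alternatives were 50% reciprocal overlap of the elements, the upper part of the scores and spans of at least 20 kb.

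The genes named are HOXD13, VEGFA, SEMA3A and NT5E, the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a mean count of at least 50 and both shHOXD13 libraries on the same side of both shNTC libraries, up to 4 members of each list past the threshold over all genes or adjusted over the list alone (otherwise the 2 of lowest p), and the 5 largest ratios each way per pair of lines among genes in the upper part of mean summed score. The rule was repeated for the count between shared anchors. Some genes that the rule names are not reported here.

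The tests were tried on simulated counts drawn for the real genes, with 200 genes changed in each of 10 draws. With each library's own anchors and a median of 5065 genes tested, edgeR recovered 4.7% of 2-fold, 61% of 4-fold and 92.7% of 16-fold changes, and called 9.5 unchanged genes per draw. Between shared anchors, with a median of 3672 genes tested, it recovered 39.8%, 89.4% and 99.8%. With 5696 genes, camera called the angiogenesis list in 10 of 10 draws when shifted by 0.5 on the log2 scale and in 0 when not shifted. Genes were drawn independently of each other, so these draws do not show how camera performs on correlated genes. No anchors were missing from single libraries in the draws. The recovered shares and unchanged genes called therefore do not cover calls that arise from such anchors. For shares of contacts, the 95% Wilson interval was within 0.206 percentage points, which covers counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.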

Results

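The series profiled how DNA folds in human melanoma cell lines described in the labels as differing in expression of HOXD13, a homeobox transcription factor of limb patterning. H3K27ac HiChIP, which captures DNA contacts at chromatin carrying a mark of active enhancers and promoters, was analysed in 4 libraries of the A375 line. Of these, 2 carried hairpins against HOXD13 (shHOXD13-2 and shHOXD13-3, 1 library each) and 2 a non-targeting hairpin (shNTC, replicates 1 and 2). Hi-C was analysed in 501mel, SKMEL-5 and SKMEL-147, with 1 library each and so no replicate error. An IgG HiChIP library of A375 was not analysed here. The shHOXD13-2 and shHOXD13-3 libraries held 954943 and 861646 contacts, and shNTC replicates 1 and 2 held 1358464 and 1349940. Contacts between different anchors (the regions called as contact ends) on 1 chromosome numbered 218252, 218909, 444018 and 383938 in that order. Anchors had been called separately per library. They covered 85.3 and 108 Mb in the shHOXD13 libraries and 199 and 189 Mb in the shNTC libraries.

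The targeted gene itself gave few contacts. At the HOXD13 promoter (chromosome 2, gene at 176087487 to 176095944, hg38), only shHOXD13-3 held an anchor, with 2 contacts to other anchors and 21 within it. Contacts at a promoter do not measure the transcript, so these counts are no check of the knockdown. VEGFA, which encodes the main angiogenic growth factor, had 5 and 4 contacts in the shHOXD13 libraries and 23 and 21 in the shNTC libraries. Its log2 fold change was -1.18 ± 0.52 (SE, n = 2 libraries per group; adjusted p = 0.204, edgeR). NT5E, which encodes the adenosine-producing surface enzyme CD73, had 0 and 12 contacts against 23 and 28, a log2 fold change of -1.02 ± 0.93 (adjusted p = 0.524, edgeR). SEMA3A, a guidance cue that restrains vessel growth, had no anchor at its promoter in any of the 4 libraries. VEGFA and NT5E did not pass the threshold, and HOXD13 and SEMA3A were not tested.

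The first comparison asked which promoters gained or lost H3K27ac contacts in the cells with HOXD13 hairpins. Zinc finger gene ZNF608 had 80 and 76 contacts in the shHOXD13 libraries against 36 and 35 in the deeper shNTC libraries, a log2 fold change of 2.23 ± 0.29 (adjusted p = 0.0170, edgeR; 1.49e-08 to 0.255 over 25 alternatives). AMOTL2, which encodes a junction protein that binds YAP, rose by 1.82 ± 0.30 (adjusted p = 0.0287, edgeR; at most 0.269 over alternatives), GSG1 rose by 1.67 ± 0.27 and the neighbours AMIGO2 and PCED1B, which share their contacts, by 1.42 ± 0.28. MRPL44, a mitochondrial ribosome gene, had no contacts in either shHOXD13 library against 119 and 109 in the shNTC libraries, at least 35.5-fold lower (adjusted p = 0.0129, edgeR; at most 0.0791 over 23 alternatives). NDUFB7, a respiratory complex I gene, and RHOA, a cytoskeletal GTPase gene counted at a window inside the gene, also had no contacts in either shHOXD13 library and were at least 36.0-fold and 36.6-fold lower. Between anchors shared by all libraries, RHOA was at -1.25 and NDUFB7 at -3.49, both still past the threshold. Each bound sets the shNTC level against a floor of 3 contacts over the shHOXD13 group, and holds only for each library's own anchors. MRPL44 had 3 and 11 contacts between anchors shared by all libraries, against 111 and 99, and was 9.68-fold lower there.

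In all, 394 of 5696 tested genes passed an adjusted p of 0.05 in edgeR, 67 higher and 327 lower in the shHOXD13 libraries. Scaling by library size alone gave 108 higher and 280 lower, and DESeq2 called 131 higher and 425 lower. Among genes with a mean count of at least 50, 127 were higher and 117 lower. The genes with the largest changes also included some whose values depended on which anchors were counted. The actin-linked genes PXN (153 and 106 contacts against 0 and 0), ANXA2 (250 and 227 against 29 and 27, counted at both gene ends) and ACTN4 (252 and 332 against 55 and 27) were called higher, PXN at least 184.6-fold. With anchors merged over the libraries, the contacts of PXN were unchanged and ANXA2 and ACTN4 were at 4.19 and 3.82, all past the threshold. A further count used only merged anchors held by all 4 libraries (shared anchors), which leaves out anchors that any library lacks. Contacts there still came only from each library's own anchors, so differences in anchor width remained. Both settings were chosen after the data were seen. Between shared anchors PXN had no contacts, and its nearest shNTC anchors lay 23.5 and 23.9 kb away. The log2 fold changes of ANXA2 and ACTN4 there were -4.09 and -1.67. These rested on 1 and 0 contacts against 17 and 14, and on 5 and 9 against 36 and 33. The semaphorin gene SEMA4A had 0 and 0 contacts against 446 and 399, yet its log2 fold change was -0.05 between shared anchors, and that of HOXB5 was 0.00. EIF3L and TWF2, both counted at a window inside the gene, and GPD1 were also at 0 in both shHOXD13 libraries and had log2 fold changes of -0.64, -0.78 and -0.90 between shared anchors, all still past the threshold. C19orf67, with 0 and 0 contacts against 124 and 76, was at -0.92 there without passing. KLHDC9, NFAT5 (counted inside the gene) and DND1 were at 0 in both shHOXD13 libraries and had no shared anchor. ANKRD10, PKM, CLIP4, CDC42EP3 and ST3GAL4 were called higher with log2 fold changes of 1.42, 1.36, 1.32, 1.30 and 1.30. Of these CLIP4 and CDC42EP3, the latter counted at both gene ends, passed between shared anchors, at 1.00 and 0.79. Without shNTC replicate 1 the count of changed genes was 29, and without shNTC replicate 2 it was 0 in edgeR, with 152 higher and 482 lower at an unadjusted p under 0.05. Without shHOXD13-2 it was 1233 and without shHOXD13-3 it was 1765.

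Between shared anchors, the genes called lower included MRPL44, which fell by 3.28 ± 0.37 on the log2 scale. CD55, which shields cells from complement, fell by 2.79 ± 0.31 (13 and 12 contacts against 131 and 135). HM13 (fell by 2.12), PABPC1L (fell by 2.09), NCKIPSD (fell by 2.04), TECR (fell by 2.03), UBE2Z, the neighbours RPN2 and MROH8 (fell by 1.88), SETD1A, a histone H3K4 methyltransferase gene, with its neighbour ORAI3 (fell by 1.84), PPM1M (fell by 1.78) and EIF4B (fell by 1.73) were also lower. Among the increases were AMOTL2 at 1.48 ± 0.22, GSG1 at 1.25 ± 0.24, TSC22D1 at 1.22 ± 0.27 and MYOF, which encodes a membrane repair protein, at 1.19 ± 0.18. PDE6A, VXN, VPS37B, the neighbours ANAPC13 and CEP63, CORO1C, HORMAD2, AMIGO2 with PCED1B, and the adenosine receptor gene ADORA2B lay between 1.01 and 1.13. ADORA2B, counted inside the gene, was at 1.02 ± 0.29 (60 and 55 contacts against 48 and 39), but at -0.15 ± 0.36 with each library's own anchors. VXN, VPS37B, HORMAD2 and, among the genes called lower, TECR were counted at both gene ends. The highest adjusted p over the 7 other settings of this count was 9.85e-07 for CD55, 0.00347 for AMOTL2 and 0.00472 for MYOF, but 0.214 for ADORA2B, 0.2587 for CORO1C and 0.446 for HORMAD2.

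**Figure D1:**
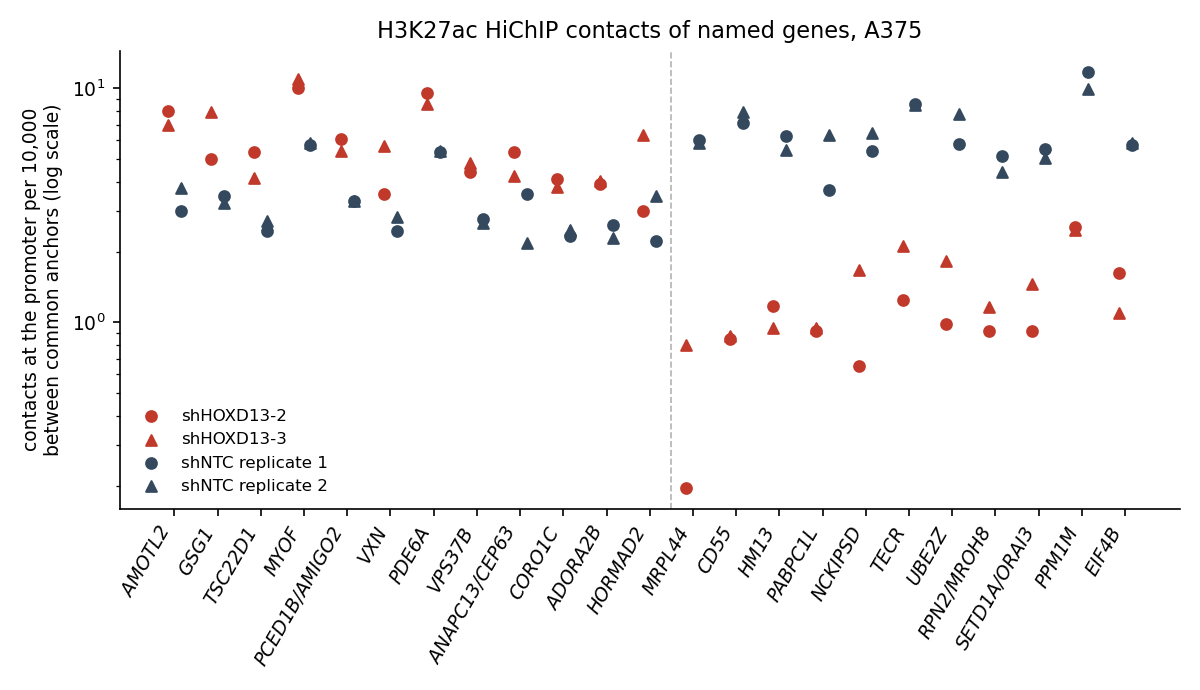
Contacts at the promoters of genes named in the count between shared anchors, per 10,000 contacts between shared anchors (log scale), for each of the 4 A375 libraries. Each point is 1 library. The shHOXD13 points lie above the shNTC points left of the dashed line, except that shHOXD13-2 lies below shNTC replicate 2 at HORMAD2, which was named on counts scaled to the sum over tested genes, and below them right of it.

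Of 3979 genes tested between shared anchors, 588 passed in edgeR, 234 higher and 354 lower. DESeq2 called 91 of them, 17 higher and 74 lower, and the count was 143 without shNTC replicate 1 and 201 without shNTC replicate 2. Of the 67 genes called higher with each library's own anchors, 49 were tested between shared anchors and 37 were called higher there. Of the 327 called lower, 218 were tested and 120 were called lower. The log2 fold change had the opposite sign there for 2 of the higher and 20 of the lower genes. The direction varied with gene density. The Spearman correlation across genes between the log2 fold change and the number of protein-coding genes within 500 kb was -0.321, where genes are not independent replicates. Genes called higher had a median of 10.5 neighbours and genes called lower 28. The same correlation was 0.160 between the shNTC replicates and -0.00913 between the shHOXD13 libraries. On chromosome 19, 76 of 401 tested genes were lower and 2 higher.

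**Figure D2:**
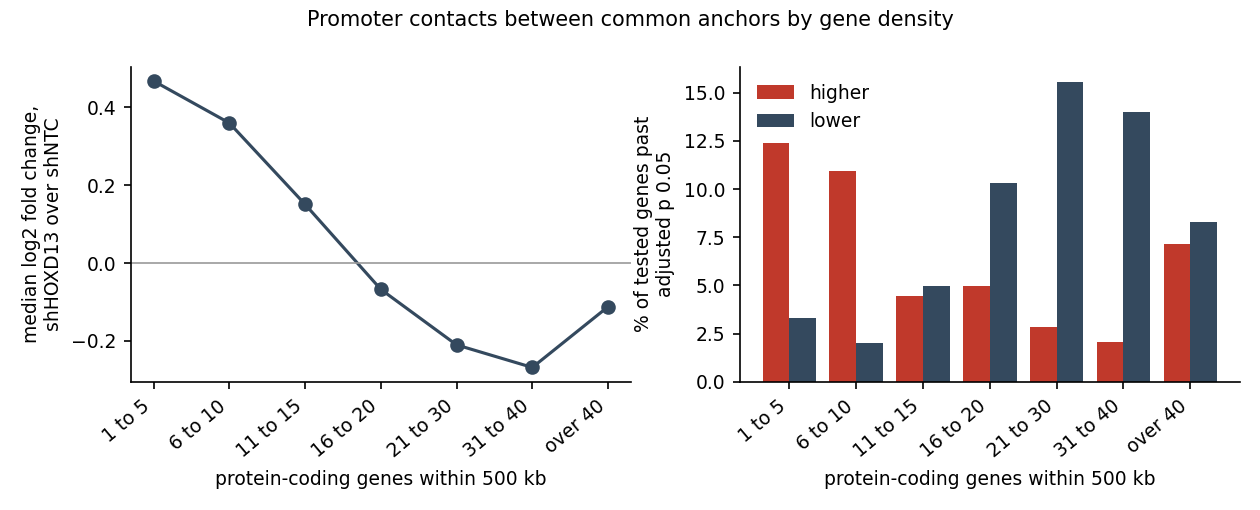
Promoter contacts between shared anchors by the number of protein-coding genes within 500 kb. Left, the median log2 fold change of the tested genes; right, the percent of tested genes called higher or lower in edgeR (adjusted p under 0.05). The median was 0.47 with 1 to 5 genes nearby, -0.27 with 31 to 40 and -0.11 with over 40, where 31 genes were called higher and 36 lower.

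Histone genes lay above 0 together. This group was noticed after the values were seen, so its test is no independent evidence. All 53 tested replication-dependent histone genes, which are transcribed in S phase, had log2 fold changes above 0 with each library's own anchors, with a median of 1.25, and 8 passed the threshold. Many of them share contacts, and the 33 distinct sets of contacts had a median of 1.29 (limma camera p = 8.2e-15 with a preset correlation of 0.01, and p = 0.124 with an estimated correlation). H2BC3 had 23 and 35 contacts in the shHOXD13 libraries against 15 and 12 in the deeper shNTC libraries (log2 fold change 2.18 ± 0.39, adjusted p = 0.0329, edgeR). H4C6 had 23 and 26 against 14 and 13, and H3C4, H2AC7 and H2BC7 together had 46 and 62 against 39 and 41. The 51 histone genes tested between shared anchors held only 26 distinct sets of contacts, 25 of them above 0, so calls among them are not independent. Between shared anchors 47 of 51 lay above 0 and 23 were called higher, but 5 with DESeq2, 3 without shNTC replicate 1 and 6 without shNTC replicate 2. With each library's own anchors, edgeR called 0 without either shNTC library in turn (14 without replicate 1 and 20 without replicate 2 at an unadjusted p under 0.05) and 0 with loops spanning at least 20 kb (19 unadjusted), and DESeq2 called 13 with all libraries. Of these genes edgeR called 36 higher without shHOXD13-2, and 15 higher and 1 lower without shHOXD13-3, where 54 of 58 lay above 0. The median stayed above 0 under all 25 other settings of the gene count, from 0.60 to 1.91 when the settings of the shared count are included. Most lie on chromosome 6, where the 10 other tested genes between 20 and 40 Mb had a median of -0.08 between shared anchors.

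**Figure D3:**
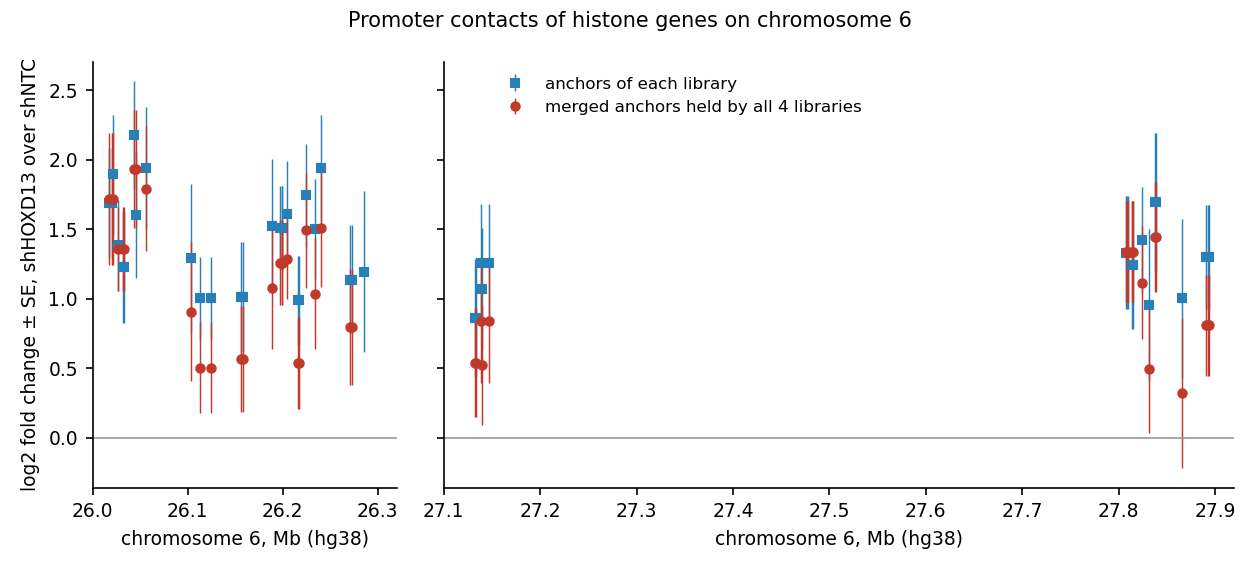
Log2 fold change of promoter contacts, shHOXD13 over shNTC, for replication-dependent histone genes along chromosome 6 (hg38). Squares use the anchors of each library, circles the merged anchors held by all 4, bars are standard errors and n = 2 libraries per group. All of the plotted values lie above 0.

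The gene lists asked whether programs of angiogenesis, immune evasion and development shifted together. Of 19 tested members of the angiogenesis and vessel guidance list, THBS1, a secreted inhibitor of vessel growth, rose by 2.18 ± 0.34 (71 and 54 contacts against 29 and 30, adjusted p = 0.0281, edgeR) and ID3, a transcriptional inhibitor active in endothelium, by 1.46 ± 0.32 (adjusted p = 0.0408). Adjusted over the list alone, 3 members were higher and 1 lower: PLAU, a protease gene, joined at 1.33 and VEGFB at -2.92 (both adjusted p = 0.0387 over the list, edgeR), though neither passed between shared anchors, with PLAU at 1.08 ± 0.52 and VEGFB at -0.25. The list's median was 0.54. It did not pass limma camera (adjusted p = 0.0972; adjusted p = 0.838 with an estimated correlation). Over its 15 alternatives the adjusted p ran from 0.0077 to 0.866.

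Of the 11 tested members of the immune evasion and adenosine list none passed, over all genes or adjusted over the list alone. PDCD1LG2, a ligand of the PD-1 receptor, was at 1.60 ± 0.54 and NECTIN2 at -1.10 ± 0.53. None of the 10 tested members of the antigen presentation and interferon response list passed, with IFIT2 at 1.31 ± 0.51 and NLRC5 at -1.79 ± 0.88. In the HOXD cluster list, which includes flanking genes, 3 members were tested and none passed, with AGPS at 0.64 and HNRNPA3 at 0.58. Of 21 tested HOXA, HOXB and HOXC genes, HOXB5 was the only call, with 0 and 0 contacts against 138 and 98, at least 36.8-fold lower, a call absent between shared anchors. The median of that list was 0.28, also with HOXB5 at its bound, the mean -0.10 and the direction in camera up (adjusted p = 0.324). None of 5 limb development genes passed, with PRRX1 at -1.94 ± 0.90 and MEIS2 at 0.88 ± 0.41. Of 9 melanocyte differentiation genes, BCL2A1, an anti-apoptotic target of MITF, had 0 and 1 contacts against 17 and 26 and a log2 fold change of -4.15 ± 0.97, lower over the list alone (adjusted p = 0.0325, edgeR) and not over all genes (adjusted p = 0.0513). That list's median was 0.31 and its mean -0.32. Of 17 genes of dedifferentiated and invasive melanoma none passed, with TEAD1 at -1.13 ± 0.37 and VIM at 1.13 ± 0.41. Of 16 MAPK output genes none passed, with DUSP4 at 0.82 ± 0.24 and DUSP6 at 0.91 ± 0.29. Of 17 housekeeping genes none passed, with EEF1A1 at 1.32 and RPLP0 at 0.87. ACTA2, at 0.24, was the only tested gene from the list of other cell types of skin and tumour. Adjusted p values of the remaining lists in camera ran from 0.324 to 0.999. Mean and median had opposite signs in the antigen presentation list, at -0.0038 and 0.09, beside the lists named above.

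**Figure D4:**
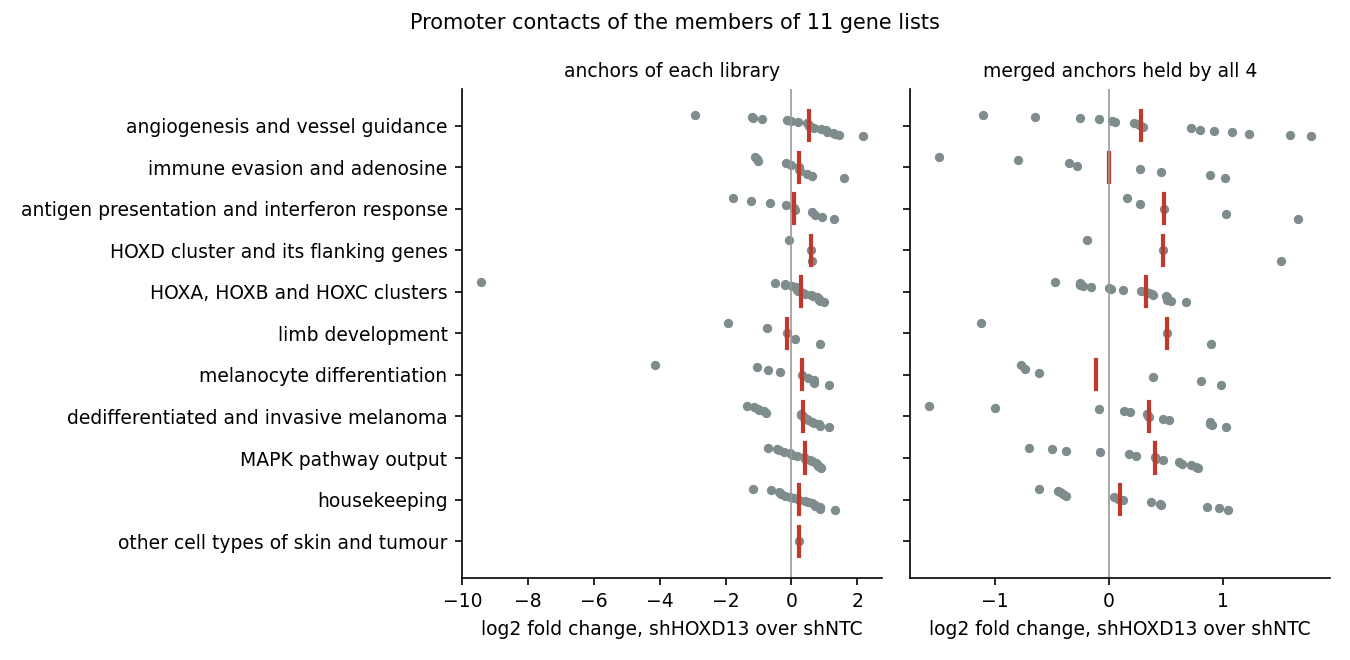
Log2 fold changes of promoter contacts, shHOXD13 over shNTC, for the tested members of 11 gene lists, counted with the anchors of each library (left) and between merged anchors held by all 4 (right). Grey points are genes and red bars list medians. The angiogenesis list had a median of 0.54 on the left and 0.28 on the right.

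Counted between shared anchors, members of several lists passed that had not passed with each library's own anchors. SOX10, the neural crest regulator, was at -0.73 ± 0.13. AXL, a receptor of drug-tolerant melanoma, was also lower, and TEAD1, a partner of YAP, was at -1.58 ± 0.43. PHLDA1 was at 0.76 ± 0.13, DUSP6 at 0.72 ± 0.25, EPHA2 at 0.80 ± 0.23, CAV1 at 1.02 ± 0.30, VIM at 0.90 ± 0.33 and FOSL1 at 0.53 ± 0.16. TGFBI was at 0.88 ± 0.25, but at -1.35 ± 0.92 with each library's own anchors (0 and 32 contacts against 102 and 70). IFIT2 was at 1.66 ± 0.57 (12 and 13 contacts against 11 and 1) and HNRNPA3 at 1.51 ± 0.44 (14 and 31 against 15 and 9). Of their 21 and 23 alternatives, IFIT2 and HNRNPA3 passed in this 1 only. THBS1 and ID3, which had passed before, were at 1.77 ± 0.32 and 1.58 ± 0.39. These genes were looked up after the values were seen.

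Pairs of anchors were compared next, to find single contacts that changed. Between shared anchors, the contact of the anchor at the promoter of DHX9, a helicase gene (chromosome 1, 182837873 to 182851762), with the anchor at 182854662 to 182879490 had 0 and 0 counts in the shHOXD13 libraries against 63 and 41. The contact of the shared RPN2 and MROH8 promoter anchor with its neighbour on chromosome 20 had 1 and 2 counts against 57 and 54. A contact at the MYOF promoter on chromosome 10, between anchors at 93434207 to 93441488 and 93457082 to 93484229, had 48 and 54 counts against 25 and 19, a log2 fold change of 1.43 ± 0.32. In all, 328 of 2352 tested pairs of shared anchors passed in edgeR, 94 higher and 234 lower. With anchors placed in 10 kb bins, the test set before the data were examined, 1234 of 3733 pairs passed, 693 higher and 541 lower, of which 613 had no contact in either shNTC library and 372 none in either shHOXD13 library. Only 369 anchors had identical coordinates in all 4 libraries. Leaving out any 1 of the 4 libraries gave 0 changed pairs in edgeR, with 1119 to 2608 at an unadjusted p under 0.05. On simulated counts the bin-pair test recovered 0% of 4-fold and 35.1% of 64-fold changes, with a median of 2431.5 pairs tested.

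The spans of loops were compared as shares of contacts, in a design that cannot pass 0.05. Loops spanning under 20 kb held 39.2% ± 2.09 (SD, n = 2) of contacts between anchors in the shHOXD13 libraries and 35.9% ± 0.540 (n = 2) in the shNTC libraries. Loops over 1 Mb held 12.7% ± 0.175 against 14.1% ± 0.240, and those of 100 kb to 1 Mb 22.9% ± 0.730 against 23.9% ± 0.2595. In these 3 classes both shHOXD13 libraries lay on 1 side of both shNTC libraries (two-sided exact permutation p = 0.3333, the smallest that 2 against 2 libraries can give). Loops of 20 to 100 kb held 25.3% ± 1.54 against 26.1% ± 0.041 (exact permutation p = 1). Of the loops, 71.3% and 71.6% in the shHOXD13 libraries and 73.7% and 72.0% in the shNTC libraries held 1 contact. Among loops with at least 2 contacts, the share over 1 Mb was 0.983% against 1.65%, so that class was mostly single contacts. Among loops present in all 4 libraries, the share under 20 kb was 57.8% against 57.0%. Among anchors overlapping an anchor of every library, a setting chosen after the data were seen, it was 39.1% against 29.7%. In that last setting all 4 classes separated the groups (exact permutation p = 0.3333).

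The Hi-C files of the 3 lines list a score of each 500 bp element for a 500 bp target window at a promoter. Scores at a window sum to at most 0.996. At HOXD13, no element was listed in 501mel, 5 were listed in SKMEL-5 with a summed score of 0.643, and 7 in SKMEL-147 with 0.396. The top element of SKMEL-5 lay 5.01 kb from the promoter (chromosome 2, 176097480 to 176097979, score 0.467), and that of SKMEL-147 overlapped it with a score of 0.0973. HOXD8 and HOXD9 had no listed element in 501mel either, with summed scores of 0.624 and 0.560 in SKMEL-5 and 0.115 and 0.166 in SKMEL-147. SEMA3A had no listed element in 501mel, 11 in SKMEL-5 (summed score 0.759) and 12 in SKMEL-147 (0.584). VEGFA had 4, 7 and 10 listed elements in 501mel, SKMEL-5 and SKMEL-147, with summed scores of 0.222, 0.380 and 0.4998, and NT5E had 8, 4 and 9, with 0.728, 0.322 and 0.620. The files list no score under 0.02, and a gene without a listed element is not shown to lack contacts.

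Melanocyte differentiation genes had lower summed scores in SKMEL-147 than in 501mel. The median log2 ratio over 15 listed members was -0.50, at the 0.05th percentile of 10000 random lists of that size, with 12 members below 0. ERBB3 was at -1.10, RAB38 at -0.71, MC1R at -0.70, MLANA at -0.63 and MITF, the lineage regulator, at -0.50, while PAX3 was at 0.68. With the highest score in place of the sum, the list stood at the 90.3th percentile. In SKMEL-5 against 501mel the list's median was -0.01 (1.395th percentile). MAPK output genes stood at the 0.33th percentile in SKMEL-5 against 501mel (median -0.08) and at the 99.03th in SKMEL-147 against SKMEL-5 (median 0.15), but with the highest score at the 45.5th (median 0.27) and the 13.4th (median -0.59). In SKMEL-147 against SKMEL-5, immune evasion genes stood at the 99.07th percentile (median 0.21), but at the 92.3th with the highest score and the 54.8th with the number of links. Dedifferentiated melanoma genes stood at the 98.35th (0.07), but at the 37.8th with the highest score (median -0.46) and the 44.4th with the number of links. The other 27 list medians, which include angiogenesis, antigen presentation, HOX, limb, housekeeping and other cell type genes, lay between percentiles 3.35 and 96.97, though some passed a bound under an alternative, such as antigen presentation (0.025) and angiogenesis (99.72) with the number of links in SKMEL-147 against SKMEL-5. With 33 medians compared and 1 library per line, these percentiles are descriptive.

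**Figure D5:**
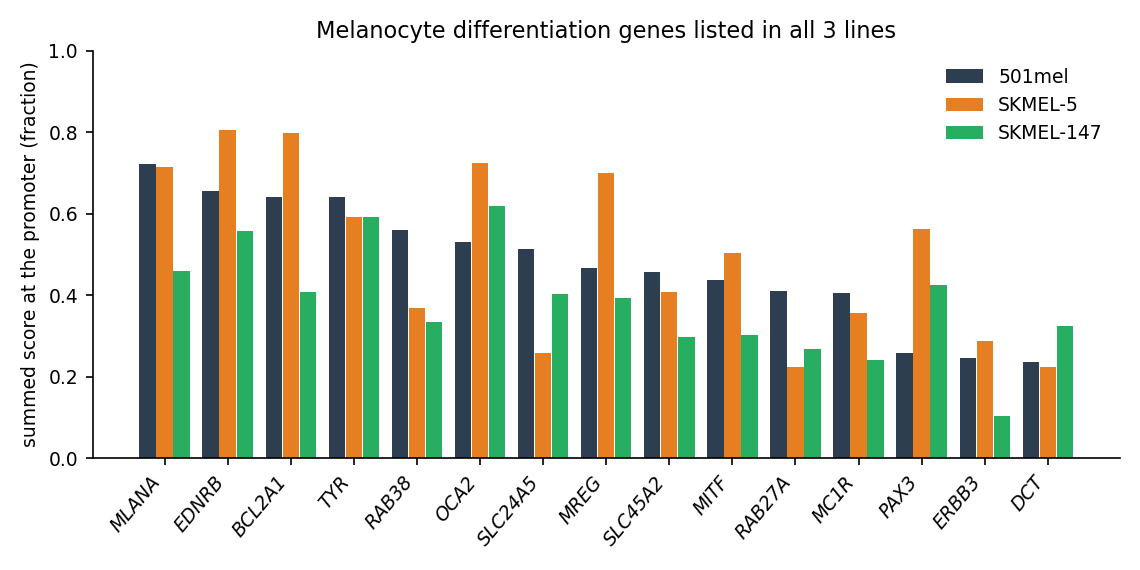
Summed score at the promoter (a fraction) of the 15 melanocyte differentiation genes listed in all 3 lines, with 1 Hi-C library per line. The SKMEL-147 bar is lower than the 501mel bar for 12 genes.

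The following genes had the largest ratios between lines among those listed in both lines of a pair and in the upper part of mean summed score. LRPAP1, which encodes a chaperone of lipoprotein receptors, had a summed score of 0.0223 in SKMEL-147 against 0.353 in 501mel and 0.647 in SKMEL-5. PBLD and its neighbour HNRNPH3 were also lowest in SKMEL-147, with PBLD at 0.0450 against 0.469 and 0.720. TSPAN5 and IL13RA1, an interleukin receptor gene, were lowest in SKMEL-5, at 0.0340 and 0.0305 against 0.639 and 0.538 in SKMEL-147. In SKMEL-5, CSTF2T (0.919) and the melanoma antigen gene MAGEC1 (0.932) were over their values in 501mel of 0.0524 and 0.0535. SMPD2, PPIL6 and SRGAP2 were lower in SKMEL-5 than in 501mel, with log2 ratios of -3.82, -3.82 and -3.30. OR10J5 was higher in SKMEL-5 and SKMEL-147 than in 501mel, at 3.37 and 3.49. In SKMEL-147, ECPAS was at -2.60 against 501mel, GLIPR1 and MRPL35 were at -2.77 and -2.56 against SKMEL-5, and TMEM18, SLC35E2B and GLRX3 at 3.397, 2.73 and 2.70. For each gene named so far in this paragraph, the lower sum of the pair rested on 1 or 2 listed elements. That of OR10J5 in 501mel was 1 element with a score of 0.02001. Scores under 0.02 are not listed, so the size of these ratios is uncertain. With 10 times the pseudocount, the log2 ratios of OR10J5 were 1.43 in SKMEL-5 and 1.52 in SKMEL-147. USP17L17, USP17L13, USP17L12, GAGE2A and CKMT1B also ranked among the largest ratios, but near-identical copies of these genes exist, which makes their scores uncertain. Whether the other genes named here, such as SRGAP2 and SLC35E2B, have such copies was not examined.

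Across the 11117 genes listed in all 3 lines, the Spearman correlation of summed scores across genes was 0.651 for SKMEL-5 and 501mel, 0.566 for SKMEL-147 and 501mel and 0.537 for SKMEL-147 and SKMEL-5. The median log2 ratios were 0.26, 0.14 and -0.10 in that order, and 2039, 1927 and 2214 genes differed by over 2-fold. With 10 times the pseudocount, 295 and 275 genes differed by over 2-fold from 501mel in SKMEL-5 and SKMEL-147.

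Most links were listed in 1 line only. Of the 252743 links of 501mel, 252499 of SKMEL-5 and 283741 of SKMEL-147, 61.3%, 63.4% and 74.2% matched no link of another line. A match needed overlapping target windows and overlapping elements. Of the elements of 501mel, 41.7% overlapped an element of SKMEL-5 and 41.7% one of SKMEL-147. For SKMEL-5 elements the shares were 65.2% in 501mel and 51.2% in SKMEL-147. For SKMEL-147 elements they were 32.9% in 501mel and 25.9% in SKMEL-5. Links of elements without such an overlap could not match, whatever their contacts. Links found in all 3 lines made up 11.4%, 11.4% and 10.1%. These had higher scores, with medians of 0.0566, 0.0840 and 0.0492 against 0.0307, 0.0355 and 0.0321 for links in 1 line only. 501mel and SKMEL-5 shared the largest part, 28.8% and 28.9% of their links. Links spanned a median of 77.7 kb in 501mel, 171 kb in SKMEL-5 and 79.2 kb in SKMEL-147.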

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

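Of the tests in this part, the limit on anchor width was set before its result was seen, and the other 5 were chosen after the results were seen.

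Contacts within 1 anchor were outside the comparisons of the report. They made up 74.15% and 71.1% of all contacts in the shHOXD13-2 and shHOXD13-3 libraries, above both shNTC libraries (60.92% and 65.63%). With 2 libraries per group the exact permutation p was 0.3333, the smallest possible. No explanation was tested.

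PXN and ACTN4 had contacts in both shHOXD13 libraries and few or none in the shNTC libraries. Whether the processing left broad domains out of the shNTC anchor lists cannot be told apart from an effect of the hairpins. Of the shHOXD13 domains of at least 30 kb, 15% in shHOXD13-2 (3 of 20) and 18.75% in shHOXD13-3 (6 of 32) touched no shNTC anchor, against 0.2236% and 0.2445% at 6 to 20 kb (Fisher exact p = 2.83e-05 and 1.19e-09), and the reverse shares at 30 kb and wider were 0.5208% and 0.6192%. An upper limit on the width of joined domains is argued against, since the widest shNTC domain spanned 169 kb. Domains join anchors up to 3 kb apart, so this test cannot decide on a limit for single anchors. The widest single anchors spanned 63.45 and 69.5 kb in shNTC replicates 1 and 2, and 48.09 and 64.8 kb in shHOXD13-2 and shHOXD13-3. What keeps the question of left-out domains open is that no promoter lay in the 2 domains of at least 30 kb without an shNTC anchor held by both shHOXD13 libraries. The ACTN4 domain spanned 87.1 and 66.4 kb, but in shHOXD13-2 it overlapped an shNTC anchor, and that of PXN spanned only 8.52 and 8.03 kb. ANXA2 also had more contacts in the shHOXD13 libraries, 250 and 227 against 29 and 27, counted at both gene ends. At the 1 end examined (60347151), which was not shown to be the promoter, its domain spanned 1.66 and 1.81 kb in the shHOXD13 libraries. In the shNTC libraries it spanned 12.4 and 13.8 kb.

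More promoters were called lower than higher, 327 against 67, though not among genes with a mean count of at least 50 (117 against 127). The part of fewer and narrower anchors in the shHOXD13 libraries cannot be told apart from an effect of the hairpins. Of the calls between shared anchors 60.2% were lower, against 83% with each library's own anchors. The number of lower calls did not fall (354 of 3979 tested genes against 327 of 5696), while higher calls went from 67 to 234. The shared count still took contacts only from each library's own anchors, so it cannot decide on narrower anchors. The smaller number of contacts in the listed loops, with anchors held as called, is argued against. After all libraries were thinned to the same total, 84.6% of calls were lower. Thinning did not change the anchors, so it cannot decide whether depth acted through the number of anchors called.

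Between shared anchors, contacts were lower in gene-dense and higher in gene-poor regions. Whether this is a library bias that follows gene density cannot be told apart from an effect of the hairpins, because the correlation with gene density was 0.16 between the shNTC replicates, neither near 0 nor as large as the -0.321 between the groups. The trend as the source of all calls is argued against: with offsets fitted to gene density, 62.1% of the calls were kept.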

How the results depend on the processing

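Settings that use merged anchors, contacts within anchors or between chromosomes, loops under 2 Mb, located promoters, scaling to all contacts on 1 chromosome or gene density were chosen after the data were seen, as were all alternatives of the count between shared anchors. Unless stated, the cause of a change was not tested. No paired analysis was possible because the hairpin numbers of the shHOXD13 libraries and the replicate numbers of the shNTC libraries do not mark pairs. Where a library was left out, the lone library was assumed to vary like the other group.

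Of 1076 values of named genes counted with each library's own anchors, 900 kept direction and side of the threshold, 110 no longer passed, 45 newly passed and 21 reversed. Between shared anchors 166 of 196 kept both and 30 no longer passed. All 126 score ratios of named genes kept their direction.

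The count of changed genes was 244 with a mean count of at least 50 (127 higher, 117 lower), where fewer genes were tested, 177 with loops present in all 4 libraries (37 and 140), 1112 with a likelihood ratio test (384 and 728), 628 for contacts within merged anchors held by all 4 (130 and 498) and 216 with contacts between chromosomes (17 and 199). Genes called higher numbered 131 with DESeq2, 108 with library size only, 102 with loess offsets, 42 with no low-count filter, 124 with loops of at least 2 contacts, 31 with loops spanning at least 20 kb, 41 after thinning, 149 with merged anchors, 234 with merged anchors held by all 4, 41 within anchors only (544 lower), 41 with located promoters only, 26 with scaling to all contacts on 1 chromosome and 43 with gene density offsets. Scaling to all contacts on 1 chromosome moved the median log2 fold change of all genes to -0.284. Without 1 library the count ran from 0 (without shNTC replicate 2, edgeR, with 152 higher and 482 lower at an unadjusted p under 0.05) to 1765 (without shHOXD13-3), higher from 0 to 424 and lower from 0 to 1341. Between shared anchors DESeq2 called 91 (17 higher, 74 lower), and without 1 library the count ran from 143 (without shNTC replicate 1) to 711 (without shHOXD13-3), higher from 22 to 223 and lower from 121 to 488.

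Changed anchor pairs numbered 0 with no filter beyond a total count of 10 (0 higher, 0 lower in edgeR, 5992 at an unadjusted p under 0.05; DESeq2 was run only with the filter and called 1350), 78 with identical anchors (38 higher, 40 lower), where 81 were tested, 271 with loops spanning at least 20 kb (127 and 144), 659 with merged anchors (143 higher) and 328 with merged anchors held by all 4 (94 and 234). With 25 kb bins 457 were higher and 951 lower. Without any 1 library the count was 0, and 0 in each direction, in edgeR, with 1119 to 2608 at an unadjusted p under 0.05.

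The angiogenesis list passed in camera with loess offsets (adjusted p = 0.0416), a promoter window of 5000 bp (0.0077) and merged anchors (0.00951), in a range of 0.0077 to 0.866 over 15 alternatives, and the HOXA, HOXB and HOXC list with merged anchors (0.00229; range 0.00229 to 0.921). An estimated correlation in camera was run for 2 other counts, each library's own anchors and shared anchors. The adjusted p was then 0.838 and 0.697 for the angiogenesis list, and 0.921 and 0.741 for the HOXA, HOXB and HOXC list. With merged anchors HOXA3, HOXA5, HOXA6 and HOXA7 shared their contacts, as did HOXC4, HOXC5 and HOXC6. No list below passed under any of its 15 alternatives. The limb development list changed direction with fry (0.62), library size only (0.98), loess offsets (0.886), merged anchors (0.916), gene density offsets (0.847) and those offsets between shared anchors (0.769), immune evasion with loops spanning at least 20 kb (0.951), melanocyte differentiation with merged anchors (0.978), the HOXD list with gene density offsets (0.987) and MAPK output with those offsets between shared anchors (0.769). Without 1 library the adjusted p ran from 0.328 to 0.911 for antigen presentation, 0.752 to 0.866 for limb development and 0.523 to 0.897 for melanocyte differentiation, each with a change of direction.

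With loops present in all 4 libraries, the difference in share of contacts was 0.0617 percentage points at 100 kb to 1 Mb and 0.00983 over 1 Mb, opposite to the main values. At 20 to 100 kb it ran from -1.91 to 0.262 without 1 library.

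Named genes reversed as follows. Between shared anchors, and for contacts within them, the log2 fold change of ANXA2 was -4.09 and -4.59, and the log2 fold change of ACTN4 was -1.67 and -2.12. The log2 fold change of PKM was -0.962 with loops of at least 20 kb, -1.52 within anchors only and -0.282 within shared anchors. The log2 fold change of CLIP4 was -0.721 with loops of at least 20 kb, and the log2 fold change of CDC42EP3 -0.402 with loops present in all 4 libraries. The log2 fold change of SEMA4A was 0.0949 with merged anchors and 0.541 within shared anchors, and the log2 fold change of HOXB5 0.00357 between shared anchors. Within anchors only and within shared anchors, the log2 fold change of IFIT2 was -0.185 and -0.328, the log2 fold change of AGPS -0.561 and -0.0185, and the log2 fold change of MEIS2 -0.672 and -0.295. Without 1 library the log2 fold change of HNRNPA3 ran from -0.0561 (without shHOXD13-3) to 0.914, and the log2 fold change of ACTA2 from -0.687 (without shHOXD13-3) to 0.71.

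For the lines, genes differing by over 2-fold made up 2.654%, 2.474% and 3.373% with 10 times the pseudocount, which shrinks ratios of low sums by construction, and 8.582%, 9.779% and 11.07% with the number of links (18.34%, 17.33% and 19.92% in the report's setting), for SKMEL-5 and SKMEL-147 against 501mel and SKMEL-147 against SKMEL-5. With the highest score in place of the sum, the melanocyte list moved to the 63.3th percentile in SKMEL-5 and the 90.3th in SKMEL-147 against 501mel, and in SKMEL-147 against SKMEL-5 the dedifferentiated list moved to the 37.8th (44.4th with the number of links) and MAPK output to the 13.4th. Of 30 percentiles under alternatives of lists past a bound, 18 stayed past it, 7 no longer passed and 5 reversed. Of 135 of the lists within the bounds, 6 passed a bound. In SKMEL-147 against SKMEL-5 these were, with the number of links, antigen presentation (0.025), angiogenesis (99.72) and HOXD (0.335), with the upper part of the scores HOXA, HOXB and HOXC (0.39), and with the highest score other cell types (98.22), which in SKMEL-5 against 501mel stood at 2.105.

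Links in both other lines, for 501mel, SKMEL-5 and SKMEL-147, made up 10.74%, 10.73% and 9.568% with 50% reciprocal overlap, 11.97%, 11.99% and 10.66% with the upper part of the scores, and 8.02%, 6.944% and 7.277% with spans of at least 20 kb. Links in neither made up 62.65%, 64.71% and 75.19%, then 59.86% and 73.53% for 501mel and SKMEL-147 with the upper part, and 66.76%, 69.49% and 79.65% with spans of at least 20 kb.

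On simulated counts at the depth of these libraries, the test of 10 kb bin pairs recovered 35.1% of 64-fold changes, whereas the gene test between shared anchors recovered 39.8% of 2-fold changes.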

Other observations

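The values in this part were looked up after the results were seen. Other HOX genes also differed between the lines in which elements were listed. HOXA13 had listed elements only in SKMEL-5 (10, summed score 0.3727). HOXA10 had 4 and 6 in 501mel and SKMEL-5 and none listed in SKMEL-147, and HOXD12 4 and 4 and none. HOXB3 had 14 in SKMEL-5, 7 in SKMEL-147 and none listed in 501mel. On chromosome 13, 7 of 35 tested genes were higher and 0 lower between shared anchors. Both shHOXD13 libraries held 2 domains of at least 30 kb without an shNTC anchor, on chromosome 3 (149571503 to 149663255) and chromosome 11 (126399239 to 126435436).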
